A study of Mus musculus with 5 samples.

How the data were processed

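Total RNA of 5 cultures was measured on one-colour Affymetrix mouse expression arrays, with biotin-labelled cRNA made from 8 µg of total RNA, per the labels' protocols. Groups were formed from the sample titles, G9C8 clone (3 arrays) and NOD.G9C8 transgenic (2 arrays). The labels describe 3 separate frozen vials of the clone and spleen cells of 2 separate mice, so that p-values cover the spread between vials of 1 clone and between 2 mice. The labels call the cells CD8 T cells and name no sort between the culture and the extraction of RNA. Scan dates, batches and the sex of mice and clone are not given in the sources used here.

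The deposited values are array intensity on a linear scale, 1 signal per probe set, and come from the Affymetrix software GCOS, per the submitters' processing notes, with its version not given. The values themselves show that every array was scaled: the 2% trimmed mean over all probe sets is 500 on each of the 5 arrays. They were therefore used as deposited, without a further normalization. The table holds no detection calls, so it does not say which probe sets lay above background. The number of arrays limits the precision of each value. No array was a copy of another: 85 to 159 probe sets had identical values in any pair of arrays.

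Of 45101 probe sets, 64 are Affymetrix controls and were left out of the fit; 34945 are paired with 1 gene symbol in the platform annotation, 932 with several and 9160 with none. Only probe sets with 1 symbol name a gene. Symbols were compared with a RefSeq gene table of assembly GRCm38.p6 through the gene identifier, which changed 0 of them. That table was otherwise used for chromosomes and to match members of the gene lists by symbol or synonym. Of 450 genes on the lists, 47 had no probe set named here, and they were not analysed here.

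Values were taken as log2(signal + 20), so that differences of dim genes are understated. Probe sets were kept at a mean signal over the 5 arrays of at least 88.2, the 40th percentile over probe sets other than controls, and each gene was represented by its brightest probe set, which left 12446 of 18193 genes. Of these, 5612 have several probe sets, and 204 called genes have a probe set that differs by over 0.5 on the log2 scale in the opposite direction. Groups were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, two-sided, as clone minus transgenic. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The fit has 3 residual degrees of freedom and 8.36 in total after moderation. Intervals are 95% confidence intervals of the fit.

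Before the data were examined, 30 gene lists were fixed: T cell functions, pathways and markers of other cell types that a spleen culture could hold. Those with at least 3 tested genes, 29 in all, were tested with limma's camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With an estimated correlation camera also lowers the degrees of freedom of its test to the 3 residual ones of the fit, so that both changes enter its p-values. A further count adjusts the p-values over each list alone. The rule for named genes was fixed at the same time. It takes the 10 largest differences in each direction among called genes whose groups do not overlap, and up to 4 called members of each list with the largest differences. Where fewer than 2 members of a list are called, up to 2 uncalled members of highest signal are taken. Cd8a, Cd8b1, Cd3e, Cd4, Ptprc and the sex-linked genes are always named. Some genes that the rule names are left to the counts, and members outside it are given as chosen after their values were seen.

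The fit was tested on simulated data for the comparison of clone with transgenic cells, in 20 runs over 12446 genes with 200 changed in each. It recovered 38.3% of genes changed 1.5-fold, 82.7% of those changed 2-fold and 98.9% of those changed 4-fold. Of its calls, 7.91% were unchanged genes. A list of 15 genes shifted by 0.8 was called in 100% of runs and unchanged lists in 0%. The simulated noise was independent between genes and the lists were random genes, so these list rates do not cover lists whose members vary together. Far fewer genes were changed than were called in the data (5448), so the gene rates need not carry over either.

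Alternatives were quantile normalization, pseudocounts of 1 and 50, a floor of 50, no filter and a filter at the 60th percentile. Others were the mean over probe sets, leaving out probe sets marked as cross-hybridizing, testing every probe set, eBayes without trend or with robust estimation, a test against a 2-fold difference, the replicate number as a block and each array left out in turn. Leaving out X-linked and Y-linked genes was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 for the remaining computations.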

Results

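Gene expression was measured in CD8 T cells of one antigen specificity from 2 sources. One source was G9C8, a cytotoxic T cell clone that recognises a peptide of the insulin B chain and is kept in culture, represented by 3 separately frozen vials. The other was spleen cells of NOD.G9C8 mice, which carry the receptor of that clone as a transgene on the NOD background, a strain that develops autoimmune diabetes; 2 mice aged 4 to 8 weeks were used. Both were stimulated with the insulin peptide at 10 µg/ml for 3 days and then rested in IL2 at 5 IU/ml for 2 days, so that the comparison asks how the long-term clone differed from freshly activated transgenic cells of like specificity. Each vial and each mouse gave 1 array. Differences are given on the log2(signal + 20) scale as clone minus transgenic, and signals as mean ± SD over 3 clone and 2 transgenic arrays. Median signals over all probe sets were 140.7 and 141.9 on the transgenic arrays and 132.6, 132.3 and 133.0 on the clone arrays. The arrays' number limits the precision: the median standard error of a difference was 0.16 on the log2 scale.

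The cells' identity markers were bright in both groups. Cd3e, a signalling chain of the T cell receptor complex, gave 5839 ± 600 in clone and 5102 ± 316 in transgenic cells, a difference of 0.19 (95% confidence interval -0.05 to 0.43; adjusted p = 0.178). Ptprc, the leukocyte common antigen, differed by -0.02 (-0.25 to 0.21). Its mean signals, 19634 in clone and 19810 in transgenic cells, lay near the top of the arrays' range, where differences can be compressed. The CD8 coreceptor chains were lower in clone, Cd8a by a difference of -0.68 (SE 0.10; adjusted p = 0.000865; 8808 ± 492 against 14192 ± 1849) and Cd8b1 by -0.65 (SE 0.08; adjusted p = 0.000359). With the mean over all its probe sets in place of the brightest, the Cd8a difference was -0.20 and no longer passed the test (adjusted p = 0.0875). Cd4 stayed dim, at mean signals of 38.8 in clone and 44.9 in transgenic cells, below the filter level of 88.2.

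The 2 sources differed over a large part of the transcriptome. Of 12446 genes tested, 2742 were higher and 2706 lower in clone, 43.8% in all, and 6998 were not called. A difference of at least 2-fold was seen for 851 of the higher and 984 of the lower genes, and of at least 8-fold for 100 and 137. The 3 clone arrays lay wholly above or below the 2 transgenic arrays for 64.5% of all tested genes, against the 20% that chance gives, and for every called gene except 1, the condensin subunit gene Ncapg2, named here after its values were seen. Among the 10 largest differences toward clone were Csf2, encoding the growth factor GM-CSF (2840 ± 711 against 9.05 ± 0.636; difference 6.59, SE 0.22), and Tnfsf11, encoding the cytokine RANKL (1934 ± 184 against 13.4 ± 7.57; 5.88). The others were Klra7 (7.86), the cation channel gene Trpc6 (7.13), the cytochrome P450 gene Cyp2c55 (6.98), the RNA-binding protein gene Elavl2 (6.22), Tmem176b (5.87), the keratin gene Krt20 (5.87), Cited4 (5.74) and Xist (5.43). Klra7 belongs to the Ly49 receptor family, whose members are close in sequence, and its one probe set is of a type marked as cross-hybridizing, so which family member was measured is uncertain. The 10 largest differences toward transgenic cells were those of Tent5c (-6.73; 4.70 ± 1.06 in clone against 2601 ± 170), Lyz1 (-6.64), the Y-linked Eif2s3y (-6.57), the chemokine gene Ccl6 (-6.48), the costimulatory receptor gene Cd27 (-6.44; 32.4 ± 17.5 against 4386 ± 223), Cd7 (-6.38), Fgf13 (-6.20), Sidt1 (-6.00), Sptbn1 (-5.76) and Aff3 (-5.57). The order of these genes depends on the pseudocount where one group lay near background: with a pseudocount of 1 in place of 20, Trpc6 (9.69) and Elavl2 (9.19) came before Klra7 (8.82), and Eif2s3y (-8.70) before Lyz1 (-7.38). The adjusted p of these 20 genes ranged from 2.7e-08 for Xist and Cyp2c55 to 6.77e-06 for Lyz1 (limma). The lysozyme gene Lyz1 was measured by a probe set of the type marked as cross-hybridizing, and without such probe sets its difference was 0.88 and not called (adjusted p = 0.264). Ccl6 was higher on the second transgenic array than on the first (4253 against 2030), as was the myeloid marker Lyz2 (5549 against 3497). Which cells of the culture gave the Ccl6 signal is therefore uncertain. Without the first transgenic array the number of lower genes was 1768.

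**Figure D1:**
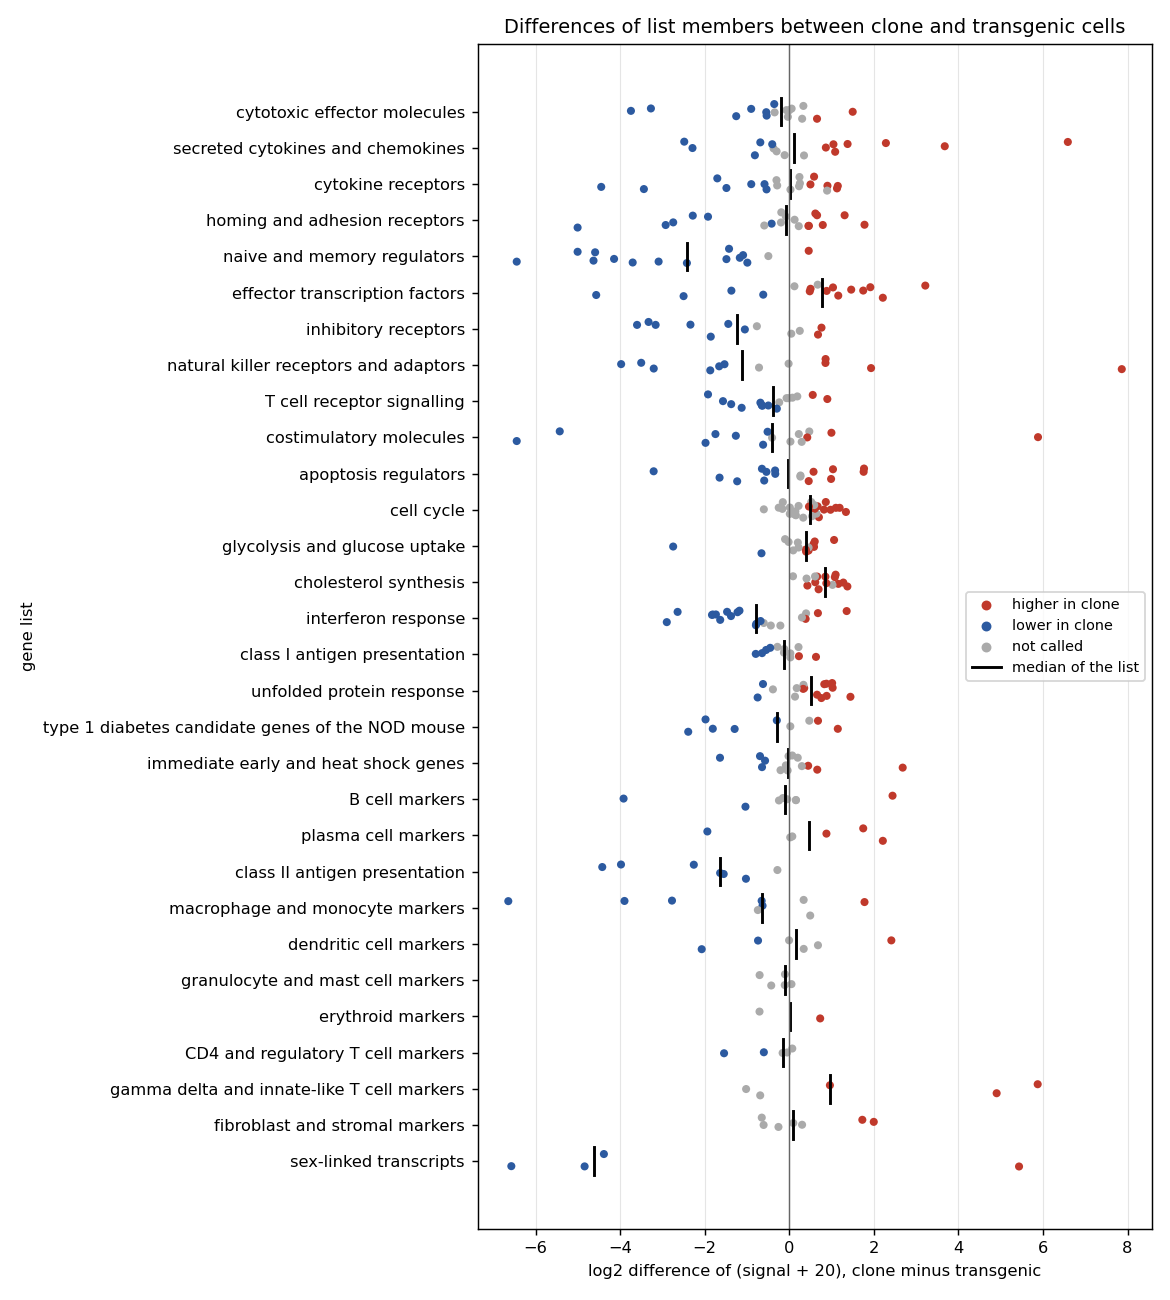
Each point is 1 tested member of a gene list (vertical axis) at its log2 difference of signal + 20, clone minus transgenic (horizontal axis), coloured by whether it was called higher, called lower or not called, and the black bar is the median of the list. The naive and memory regulators have a median of -2.42 and the cholesterol synthesis genes one of 0.86.

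Genes that mark naive and memory T cells were lower in clone almost throughout. Of the 15 regulators tested, 13 were lower, 1 was higher and 1 was not called, with a median difference of -2.42; adjusted over the list alone, 1 was higher and 14 lower. They included Cd27, the lymph node homing receptor gene Ccr7 (197 ± 57.9 against 6812 ± 997; -5.01, SE 0.21, adjusted p = 9.68e-07), the inhibitor of DNA binding Id3 (-4.63) and the transcription factor gene Myb (-4.59). The 1 higher member was the survival gene Bcl2 (0.46) and the uncalled one Bcl6 (-0.49), both named after their values were seen. Against the other genes tested, the list was lower by camera, a competitive gene set test (adjusted p = 1.03e-07), with adjusted p = 0.263 with an estimated correlation. Homing and adhesion receptors went both ways, with 7 higher, 6 lower and 6 not called among 19, and the same counts when adjusted over the list alone. Besides Ccr7, the gut homing receptor gene Ccr9 (-2.92), the integrin gene Itgae (-2.74) and S1pr1, whose product directs exit from lymphoid organs (-2.28), were lower. As a whole these receptors were not called (median -0.08, adjusted p = 0.723).

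Transcription factors of effector cells were mostly higher in clone: 10 of 16 were higher, 4 lower and 2 not called, or 11 higher and 4 lower when adjusted over the list alone. Rora, encoding a nuclear receptor, gave 6560 ± 919 against 687 ± 103 (3.22, SE 0.14, adjusted p = 1.02e-06), and Irf4, induced by receptor signalling, was higher by a difference of 2.21. Ikzf3, a member of the Ikaros family, was lower (-4.57) and so was Gata3 (-2.50). Camera did not call this list (median 0.78, adjusted p = 0.0910), although it did without a filter on dim probe sets (0.0459). Cytotoxic effector genes were divided between all outcomes. Gzmb, encoding granzyme B, gave 19535 ± 1545 in clone and 19545 ± 705 in transgenic cells (difference -0.00, -0.21 to 0.20, adjusted p = 0.981), and Prf1, encoding perforin, differed by -0.07 (-0.44 to 0.31, adjusted p = 0.769); both were named after their values were seen. Gzmb lay near the top of the arrays' range, whose highest signals were 25836 to 30579, where differences can be compressed. Gzma was lower in clone (1591 ± 161 against 21509 ± 933; -3.74, SE 0.10, adjusted p = 1.32e-07), with a transgenic signal in that upper range too, so that its difference can be understated, whereas Gzmk was higher (8472 ± 964 against 3194 ± 1669; 1.5, adjusted p = 0.00227). Gzmd was lower (-3.27), measured by a cross-hybridizing probe set in a cluster of closely related granzyme genes. Of the 16 cytotoxic genes, 2 were higher, 7 lower and 7 not called, also when adjusted over the list alone, and the list was not called (median -0.21, adjusted p = 0.213).

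Secreted cytokines and chemokines included 7 higher, 5 lower and 4 uncalled members of 16, unchanged when adjusted over the list alone. Next to Csf2, the effector cytokine gene Ifng was higher in clone (6501 ± 1122 against 522 ± 280; 3.68, SE 0.28, adjusted p = 2.37e-05), and the chemokine gene Xcl1 was lower (-2.29). As a group the cytokine genes were not called (median 0.12, adjusted p = 0.502). Il2 was dim, with mean signals of 12.4 in clone and 25.6 in transgenic cells. Among cytokine receptors 5 were higher, 7 lower and 7 not called of 19, with the same counts when adjusted over the list alone. Il6st, the shared receptor chain of the IL6 family, was lower (34.1 ± 19.0 against 1109 ± 15.9; -4.45), as were both TGF-beta receptor genes, Tgfbr1 (-3.44) and Tgfbr2 (-1.70), and Il7r (-1.49). The median of this list was 0.03, its mean -0.41 and its test pointed down without a call (adjusted p = 0.610).

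**Figure D2:**
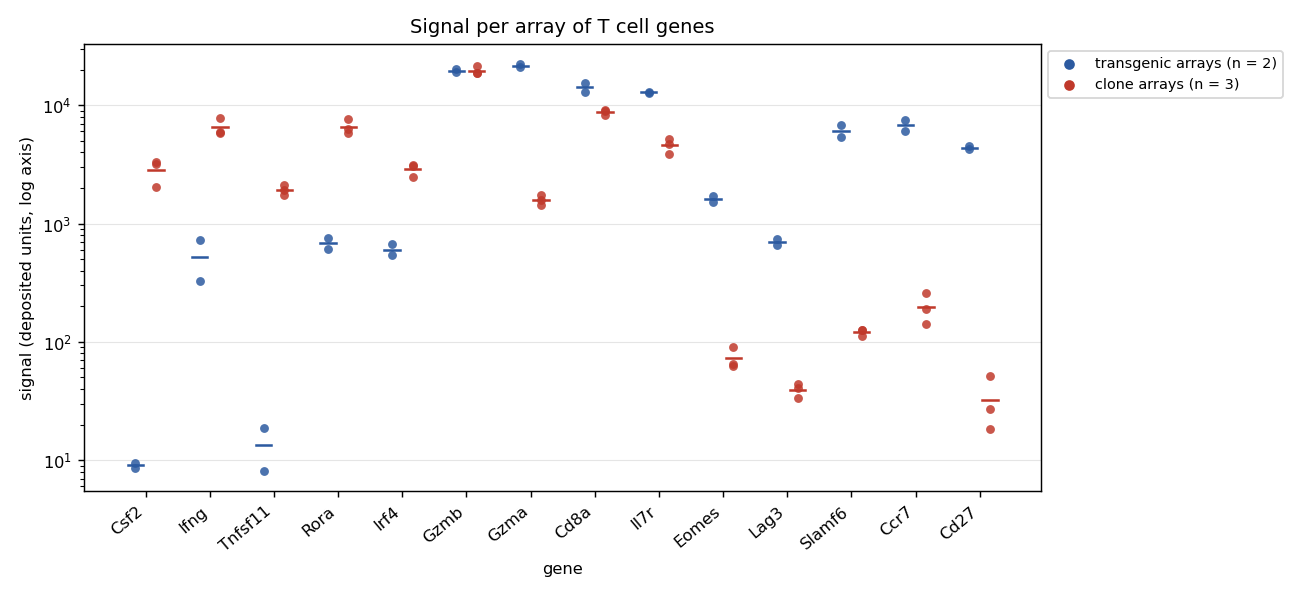
Each point is the deposited signal of 1 array on a log axis for the gene named on the horizontal axis, with transgenic arrays (n = 2) and clone arrays (n = 3) side by side, and each dash is the group mean. Csf2 lies at 9.05 on average in transgenic and 2840 in clone cells, Cd27 at 4386 and 32.4, and Gzmb at 19545 and 19535.

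Inhibitory receptors were predominantly lower in clone, with 7 of 12 lower, 2 higher and 3 not called, also when adjusted over the list alone. Lag3 (39.3 ± 5.17 against 698 ± 62.7; -3.60, SE 0.22, adjusted p = 6.89e-06), Btla (-3.33), Cd244a (-3.16) and Cd160 (-2.34) were lower, and the higher members were Ctla4 (0.68) and Entpd1 (0.76), named after their values were seen. The list was called (median -1.25, adjusted p = 0.0381), with adjusted p = 0.636 with an estimated correlation. That call ended with the stricter filter on dim probe sets (median -0.50, adjusted p = 0.308) and without the second transgenic (0.0540), the first clone (0.0633) or the second clone array (0.0527). Costimulatory molecules included 3 higher, 7 lower and 5 uncalled of 15, with the same counts when adjusted over the list alone. Slamf6, a homotypic receptor of the SLAM family, was lower (121 ± 8.58 against 6087 ± 1012; -5.43) together with Cd27 and the 4-1BB gene Tnfrsf9 (-1.98), and Tnfsf11 was higher. Costimulatory molecules as a list were not called (median -0.41, adjusted p = 0.200). Of 12 natural killer receptors and adaptors, 4 were higher, 6 lower and 2 not called, or 4 and 7 when adjusted over the list alone. The activating receptor NKG2D, encoded by Klrk1, was lower in clone (209 ± 38.9 against 2075 ± 208; -3.20, adjusted p = 3.8e-06). So were Fcgr3 (-3.98) and the adaptor gene Tyrobp (-3.50), which myeloid cells also express and which lay with the myeloid markers higher in the transgenic arrays. The list was not called (median -1.12, adjusted p = 0.265). T cell receptor signalling genes were lower in 9 of 16, higher in 2 and not called in 5, unchanged when adjusted over the list alone. The largest differences were those of the protein kinase C theta gene Prkcq (-1.92), Plcg1 (-1.57), the zeta chain gene Cd247 (-1.37) and the kinase gene Fyn (-1.13), while Zap70 (0.90) and Lcp2 (0.56), named after their values were seen, were higher. The list was called (median -0.39, adjusted p = 0.0349), with adjusted p = 0.636 with an estimated correlation, and the call ended with the mean over probe sets (median -0.25, 0.0524), with the replicate block (0.0524) and without the first clone array (0.0633).

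Part of the cell division genes and most cholesterol synthesis genes were higher in clone. Among 26 cell cycle genes 10 were higher, none was lower and 16 were not called, also when adjusted over the list alone; the higher ones included the mitotic genes Cdc20 (5805 ± 1712 against 2225 ± 426; 1.34, SE 0.24, adjusted p = 0.00233) and Ccnb2 (1.10). Mcm4, a subunit of the replication helicase, was called higher (0.98), but without cross-hybridizing probe sets its difference was -0.45 and not called (adjusted p = 0.0618). The list was called (median 0.49, adjusted p = 0.0375), with adjusted p = 0.700 with an estimated correlation. The second clone array lay below the mean of the other 2 clone arrays in 25 of the 26 genes, by a median of -0.70, and the second transgenic array above the first in 22, by a median of 0.19. Without the second clone array the median was 0.68 (adjusted p = 6.6e-06), and the call ended without the first clone (0.128), the third clone (0.119) or the first transgenic array (0.110), under quantile normalization (0.124), with the stricter filter (median 0.52, 0.0643), with the mean over probe sets (median 0.26, 0.0683), without cross-hybridizing probe sets (0.0638) and with the replicate block (0.0747). Cholesterol synthesis genes were higher in 11 of 15 and not called in 4, or higher in 12 when adjusted over the list alone, with a median of 0.86 (adjusted p = 0.000451, and adjusted p = 0.648 with an estimated correlation). Fdps (3512 ± 966 against 1310 ± 187; 1.37, SE 0.22, adjusted p = 0.00135), Insig1 (1.28), Lss (1.16) and Pmvk (1.10) led the list, and the second clone array was the lower one in all 15 genes, by a median of -0.56. Glycolysis and glucose uptake genes were higher in 7 of 15, lower in 2 and not called in 6, with the same counts when adjusted over the list alone, among them the glucose transporter gene Slc2a1 (1.06) and Pfkl (0.60); Aldoc was lower (-2.75). That list was not called (median 0.39, adjusted p = 0.0910), although it was without a filter (0.0419).

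Unfolded protein response genes were higher in 10 of 16, lower in 2 and not called in 4, unchanged when adjusted over the list alone (median 0.51, adjusted p = 0.0170, and adjusted p = 0.636 with an estimated correlation). Ddit3, a stress-induced transcription factor gene, gave 3179 ± 525 against 1149 ± 168 (1.45, SE 0.15, adjusted p = 0.000130), followed by Herpud1 (1.03), Atf6 (1.01) and Chac1 (0.88). Asns (-0.75) and Dnajb9 (-0.62) were lower, named after their values were seen. With the stricter filter the call ended (median 0.35, adjusted p = 0.0508). Apoptosis regulators went both ways, with 6 higher, 8 lower and 2 not called of 16, also when adjusted over the list alone. The death receptor gene Fas was lower in clone (74.0 ± 12.8 against 842 ± 16.1; -3.21, adjusted p = 6.94e-06), as was Cflar, an inhibitor of death receptor signalling (-1.65), and the pro-apoptotic genes Bmf (1.77) and Bbc3 (1.76) were higher. No call was made for the apoptosis list (median -0.03, adjusted p = 0.723). Immediate early and heat shock genes were higher in 3, lower in 4 and not called in 7 of 14, with the same counts when adjusted over the list alone. Atf3 was higher (2.68) and Fos lower (-1.64), and the uncalled list had a median of -0.03, a mean of 0.03 and a test pointing down (adjusted p = 0.723).

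Genes induced by interferon were lower in clone, 13 of 21, with 3 higher and 5 not called, or 4 higher and 13 lower when adjusted over the list alone. Usp18 (119 ± 19.8 against 1012 ± 126; -2.90, SE 0.19, adjusted p = 9.51e-06), Rtp4 (-2.64), Ifit1 (-1.83) and the RNA sensor gene Ifih1 (-1.81) were lower, and Mx1 (1.36), Bst2 (0.68) and Oas1a (0.39), named after their values were seen, were higher. The list was called (median -0.79, adjusted p = 0.00108), with adjusted p = 0.636 with an estimated correlation. The second transgenic array lay above the first in only 1 of the 21 genes, with a median of -0.23 for the second minus the first. Class I antigen presentation genes were higher in 2, lower in 4 and not called in 6 of 12, unchanged when adjusted over the list alone; the immunoproteasome subunit gene Psmb10 (-0.79) and Tapbp (-0.64) were lower and Tap2 was higher (0.63). The list was not called (median -0.12, adjusted p = 0.477). Among 9 candidate genes for type 1 diabetes of the NOD mouse, 2 were higher, 5 lower and 2 not called, also when adjusted over the list alone. Vav3 was lower (60.7 ± 21.9 against 395 ± 59.7; -2.39), with Tnfrsf9 and Ifih1, and the higher ones were Il2ra (1.15) and Ctla4, named after their values were seen. Slc11a1 was lower too (-1.29), but its signal rose from 308.5 on the first to 681.9 on the second transgenic array, as that of Lyz2 did. Without the second transgenic array its difference was -0.74. No call was made for the candidate genes together (median -0.29, camera adjusted p = 0.455).

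Markers of other cell types were not evenly spread over the arrays. All class II antigen presentation genes that were called were lower in clone, 6 of 7 with 1 not called and the same counts when adjusted over the list alone, among them H2-Aa (12.2 ± 7.40 against 665 ± 136; -4.42, SE 0.31, adjusted p = 1.45e-05), H2-Ab1 (-3.98) and Cd74 (192 ± 17.9 against 1011 ± 281; -2.26). The list was called (median -1.63, adjusted p = 0.000451), with adjusted p = 0.359 with an estimated correlation. Macrophage and monocyte markers were lower in 5, higher in 1 and not called in 3 of 9, or 6 and 2 when adjusted over the list alone. Lyz2 (279 ± 45.1 against 4523 ± 1451; -3.90, SE 0.21, adjusted p = 3.42e-06) and Cd14 (40.4 ± 14.5 against 396 ± 130; -2.77) were lower, and Ccr2, which T cells also express, was higher (1.78). The list was not called (median -0.65, adjusted p = 0.159), although it was without a filter (0.0355), and the second transgenic array lay above the first in 8 of the 9 genes, by a median of 0.43. Of 6 dendritic cell markers, Itgax (-2.07) and Zbtb46 (-0.74) were lower and Batf3 higher (2.41), with 3 not called and the same counts when adjusted over the list alone; Zbtb46 lost its call without the first (adjusted p = 0.0697) or the second transgenic array (0.137). Their median was 0.17 and their mean 0.10, whereas the test pointed down without a call (adjusted p = 0.994). B cell markers gave 1 higher, 2 lower and 5 uncalled of 8 in both adjustments, counted over all genes and adjusted over the list alone. Cd79b (26.7 ± 22 against 624 ± 42.8; -3.92) and Ighm (-1.04) were lower and Ebf1 higher (2.44), and the list was not called (median -0.10, adjusted p = 0.664). Ighm lost its call with the mean over probe sets (-0.29, adjusted p = 0.0897). Plasma cell markers were higher in 3, lower in 1 and not called in 2 of 6, also when adjusted over the list alone. The higher ones, Irf4, Prdm1 (1.75) and Xbp1 (0.88), are expressed by activated T cells too, and Sdc1 was lower (-1.94; list median 0.48, adjusted p = 0.200).

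None of 5 granulocyte and mast cell markers was called by limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Ltf differed by -0.11 (-0.55 to 0.34) and Ngp by -0.10 (-0.53 to 0.33; list median -0.11, adjusted p = 0.610). Only 2 erythroid markers passed the filter, too few for a list test: Gata1 was higher (0.73), also when adjusted over the list alone, and the haemoglobin gene Hba-a1 was not called (-0.70, -1.46 to 0.06). The call of Gata1 ended without the first transgenic array (adjusted p = 0.0727), and Hba-a1 was called without the third clone array (0.0497). Of 5 markers of CD4 and regulatory T cells, Gpr83 (-1.54) and Ikzf2 (-0.60) were lower and 3 were not called, also when adjusted over the list alone (list median -0.16, adjusted p = 0.502). Gpr83 lost its call without the first (0.124) or the second transgenic array (0.0578), and Ikzf2 without the first transgenic array (-0.20, 0.297), without any single clone array (0.0509 to 0.101), with the mean over probe sets (-0.46, 0.298), without a filter (0.0775) and with eBayes without trend (0.0972). Markers of gamma delta and innate-like T cells were higher in 3 of 5 and not called in 2, in both adjustments, over all genes and adjusted over the list alone. Tmem176b (15023 ± 374 against 245 ± 95.7; 5.87), its neighbour Tmem176a (4.90) and Sox13 (0.96) were the higher ones. The list was not called (median 0.96, adjusted p = 0.0910), although it was with the stricter filter (0.00548; median 4.90, the value of Tmem176a, as dimmer members fall out), without a filter (0.0375) and without the first transgenic array (0.0494). Fibroblast and stromal markers were higher in 2 and not called in 5 of 7, also when adjusted over the list alone: Dcn was at 193 ± 22.1 against 35.4 ± 22.2 (2.00) and Lum at 350 ± 214 against 78.5 ± 5.52 (1.73; list median 0.09, adjusted p = 0.723). Lum was not called without the first (0.0599) or the second transgenic array (0.0699).

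Sex-linked transcripts separated the groups completely, although the labels give no sex. Xist, expressed from the inactive X chromosome, gave 13885 ± 1061 in clone and 301 ± 19.4 in transgenic cells (5.43, SE 0.10, adjusted p = 2.7e-08). The Y-linked Eif2s3y (5.23 ± 3.20 against 2370 ± 84.2; -6.57), Uty (-4.84) and Kdm5d (-4.38) were lower in clone. All 4 were called, also when adjusted over the list alone, and the list, whose members oppose one another, was not called (median -4.61, adjusted p = 0.159).

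**Figure D3:**
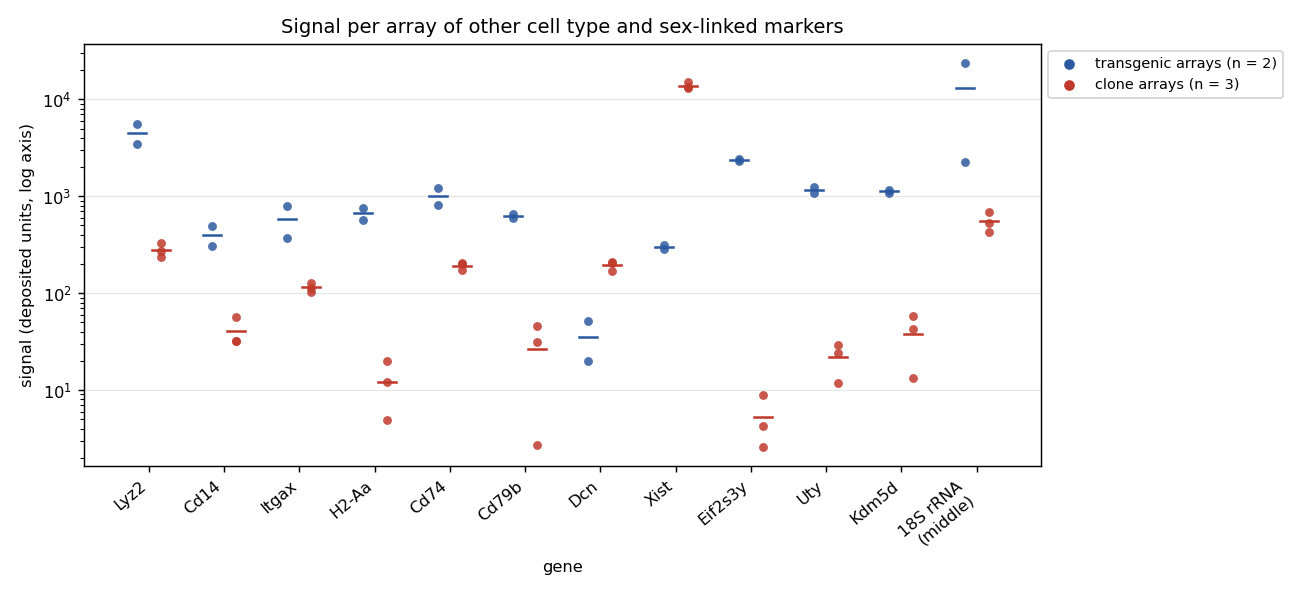
Each point is the deposited signal of 1 array on a log axis for a marker of another cell type, a sex-linked gene or the middle probe set of 18S ribosomal RNA, with transgenic arrays (n = 2) and clone arrays (n = 3) side by side and dashes for group means. Lyz2 lies at 4523 on average in transgenic and 279 in clone cells, and Xist at 301 and 13885.

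Of the 29 lists tested, camera called 8 with its preset correlation of 0.01, and none of these calls held in the setting that estimates the correlation within each list from the 5 arrays and also lowers the test to 3 degrees of freedom. The correlation is not what ended all of them: it was estimated at 0.00624 for naive and memory regulators and at -0.149 for class II antigen presentation, both below the preset. For the other called lists the estimate was above the preset. It was 0.777 for cholesterol synthesis, 0.751 for cell cycle, 0.267 for interferon response and 0.126 for T cell receptor signalling. For inhibitory receptors it was 0.0432 and for the unfolded protein response 0.0424. Where the estimate was far above 0.01, the camera p-value at the preset can be too small. The directional fry test, which asks whether the genes of a list move on balance one way and does not compare the list with other genes, called 23. Cell cycle, which camera had called, was not among them (fry adjusted p = 0.276).

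Replicates within a group were close to one another. Pearson's correlation of log2 signals across genes, which are not independent replicates, was 0.983 between the 2 transgenic arrays and 0.977 to 0.980 among the 3 clone arrays, against 0.850 to 0.861 between groups. The median over genes of the standard deviation within a group was 0.103 in transgenic cells (n = 2) and 0.156 in clone (n = 3) on the log2 scale. No test was made between these. The median of standard deviations from 2 arrays comes out lower than from 3 at equal spread, so the values do not rank the groups. The ratio of 3' to 5' signal, a sign of RNA quality, was higher on every clone array than on either transgenic array. For actin it was 1.05 and 1.05 on the transgenic arrays and 1.06, 1.14 and 1.10 on the clone arrays, and for Gapdh 0.763 and 0.775 against 0.869, 0.819 and 0.831. Signals of 18S ribosomal RNA differed more, with 23623 and 2275 on the transgenic arrays and 692, 531 and 427 on the clone arrays for the middle probe set.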

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

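The comparison of control probe sets was chosen after their values were seen. Control probe sets on the arrays were not part of the gene comparison. Of 19 mouse control probe sets with a mean signal above the filter level, 10 drew attention. Their groups did not overlap, and their log2 difference, clone minus transgenic, was larger in absolute value than any among the 18 spike-in controls. The largest of those was 0.65 in absolute value, on a BioB probe set lower in clone (100 to 144 against 208 and 176). The 3 probe sets of 18S ribosomal RNA were lower in the clone arrays, by -3.22 at the 5' end, -3.72 in the middle and -4.79 at the 3' end. On all 3 the first transgenic array lay in the upper range of the arrays' signals, so that these differences can be understated. Arrays of a group differed widely here: in that order the transgenic arrays gave 21373 and 16873, 23623 and 2275, and 22088 and 7602, and the clone arrays 688 to 6071, 427 to 692 and 377 to 514. The control for the B1 repeat, a short interspersed element of the mouse genome, was higher by 1.11 (a mean signal of 14271 in clone and 6545 in transgenic cells). The 4 probe sets of the pyruvate carboxylase gene were higher by 2.03, 0.84, 2.19 and 2.39. Those of the transferrin receptor gene were lower by -1.05 at the 3' end and -0.85 at the 5' end, whereas the middle one differed by -0.30, less than the largest spike-in control. No explanation was tested for these values.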

How the results depend on the processing

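Which alternatives were run was fixed before the data were examined, except leaving out X-linked and Y-linked genes. Among these alternatives the number of genes called was within 1.5 times 5448 except for 2. Testing every probe set called 11329 (5358 higher and 5971 lower) among 27022, by construction with more features. The test against a 2-fold difference, by construction stricter, called 721 (325 and 396). Leaving out each array in turn gave 3663 to 5492 genes, with 1895 to 2752 higher and 1768 to 2740 lower; the lowest counts came without the first transgenic array, which leaves 1 array whose spread is taken from the clone arrays. Quantile normalization gave 5541, with 53.5% higher in place of 50.3%, and 5267 were called without X-linked and Y-linked genes. With the replicate number as a replicate block 4633 genes were called (2282 higher, 2351 lower). The labels pair no vial with a mouse. The differences of the first 2 replicates correlated between groups at -0.06 across genes. That shows no shared replicate effect, but it cannot exclude handling in pairs. The third clone array, alone in its block, adds nothing to the difference. In this setting the list calls of T cell receptor signalling and cell cycle ended, the latter also when that array alone was left out. Where genes were tested, no difference of a called gene changed sign except those of 120 genes with the mean over probe sets and 26 without cross-hybridizing probe sets. Camera called 8 lists, 5 to 8 with an array left out, 6 to 12 under the other settings, 0 with an estimated correlation and 23 by fry, which tests another question. Of the named genes, Lyz1 was 0.88 and Mcm4 -0.45 without cross-hybridizing probe sets, because another probe set then stood for the gene. In the remaining comparisons of named genes 33 lost a call and 1 gained one, against 1978 unaltered; of lists, 16 lost and 6 gained one, against 468; the cause was not tested. Gzme lost its call most often, at adjusted p of 0.0507 to 0.438. Dim signals limit what can be read: near the filter level of 88.2 the pseudocount of 20 understates a difference.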

Other observations

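The gene families, the look at receptor segments and the tests of explanations below were chosen only after the results were seen; the gene lists and the alternatives they draw on were fixed before. Families were taken by gene symbol, and members known as assembly factors or parts of other complexes were left out, also after their values were seen. The families were thus tested on the same values that led to their choice. Their p-values only describe them and do not measure evidence. Subunits of several large protein complexes were higher in clone. Of 75 mitochondrial ribosomal protein genes, 42 were higher, 2 lower and the rest not called (median 0.38, camera adjusted p = 3.98e-07 over 9 families, and adjusted p = 0.211 with an estimated correlation), led by Mrpl33 (1.53) and Mrps28 (1.18). Respiratory complex I subunits were higher in 22 of 34 and lower in none (median 0.35, adjusted p = 8.78e-06, and adjusted p = 0.211 with an estimated correlation). Mitochondrial import genes were higher in 11 of 22 and lower in 2 (0.31, adjusted p = 0.00222, and 0.211 with an estimated correlation), with Timm9 at 1.26 and Tomm40 at 1.11. The cytosolic chaperonin had 6 of 7 subunits higher (0.57, adjusted p = 0.00222, and 0.262 with an estimated correlation), Cct8 by 0.97, and the proteasome 17 of 34 higher and 1 lower, Psmb10 (0.28, adjusted p = 0.00055, and 0.357 with an estimated correlation). Cytosolic ribosomal proteins had 6 higher and 2 lower of 38 and a median of -0.06, or 0.00 under quantile normalization (adjusted p = 0.876). In the other direction, Kelch-like genes were lower in 13 of 21 and higher in 2 (-0.61, adjusted p = 0.00055, and 0.211 with an estimated correlation). The Gimap family, GTPases of lymphocytes, was lower in 4 of 8 with none higher (-0.46, adjusted p = 0.0137, and 0.414 with an estimated correlation), Gimap6 by -1.01. Of 7 Schlafen genes 4 were lower and 2 higher (-1.31, adjusted p = 0.248), with Slfn2 at -1.92 and Slfn1 at -1.71. All medians except that of cytosolic ribosomal proteins kept their sign under quantile normalization. Those of complex I (0.23), the proteasome (0.21), the chaperonin (0.44) and Kelch-like genes (-0.50) came closer to 0. So, by less, did those of mitochondrial import (0.29) and Schlafen genes (-1.26).

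Probe sets of T cell receptor gene segments, 14 past the filter, differed although both sources carry one receptor by their labels: 4 were higher in clone, 8 lower and 2 not called when every probe set was tested. The 3 probe sets of the gamma segment Trgv4 were higher by 2.70, 3.56 and 4.87, the brightest of them at 7054 ± 1001 in clone (n = 3) and 579 ± 67.3 in transgenic cells (n = 2). Trbv13-2 was higher by 2.97 (2730 ± 322 against 330 ± 10.8). The 5 probe sets annotated to Trav9d-3 were lower by -0.56 to -3.87, the brightest ones at 9461 ± 538 against 14037 ± 1633 and 9094 ± 619 against 15212 ± 1253, and Trav12n-2 was lower by -1.96. Probes for segments can also bind shared constant sequence, so these values do not give the receptor in use.

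Myeloid transcripts were brighter in the transgenic arrays, and a spleen culture, for which the labels name no sort, may hold myeloid cells. The 4 macrophage and monocyte markers lower in clone other than Lyz1 (Lyz2, Cd14, Csf1r and Adgre1, none of them on another list) were all higher in the second than in the first transgenic array, by a median of 0.39, against -0.33 to 0.33 for the central 95% of 10000 random gene sets matched on signal; the shift had been seen before this test was written, so a differing share of such cells and T cells that regulate these genes together both stay open. Of the abundant macrophage genes, C1qa, C1qb and C1qc stayed dim in the transgenic arrays, with mean signals of 14.2, 54.4 and 21.1 against 12.3, 55.5 and 5.37 in clone, whereas Itgam (118 against 20.1) and Mpeg1 (99.3 against 19.2) were brighter in transgenic cells, all 5 with a mean over the arrays below the filter level. For the 6 class II genes lower in clone the same median was 0.12, with 3 higher and 3 lower. Over all 7 tested class II genes it was 0.41, with 4 higher. Transgenic cultures with a like share of cells carrying class II would show no shift between their arrays. These medians therefore cannot tell such cells apart from class II expression by the T cells, and the source of the class II signal was not tested otherwise. Probe sequence shared with Lyz2 may give the Lyz1 difference, which was 0.88 without the cross-hybridizing probe sets, where another of its probe sets stands for the gene; binding to Lyz2 itself was not tested.

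Xist and Y-linked transcripts separated the groups. A candidate explanation is a female source of the clone and male mice. The X-linked partners of Y-linked genes, Kdm6a, Ddx3x, Eif2s3x and Kdm5c, had a median difference of 0.47, all 4 above 0. It lay within the -0.37 to 0.84 that the central 95% of random sets of 4 X-linked genes span. That span is wide, so this test cannot decide, and it takes nothing from the Xist and Y-linked values. Those went the way of the candidate explanation on every array. Xist gave 13107 to 15093 in clone and 288 and 315 in transgenic cells. Eif2s3y gave 2.6 to 8.8 in clone and 2429 and 2310 in transgenic cells. The sex of animals and clone is not given in the labels, so this difference stays mixed with that between clone and transgenic cells.

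Long culture could have changed whole chromosomes of the clone. Among genes with a mean signal over 500, the median difference of an autosome lay at most 0.0789 from that of the other autosomes. That was chromosome 7, with 464 genes, and the widest bootstrap bound of any autosome was 0.16. These values argue against a gain or loss of a whole autosome in most cells of the clone. Smaller changes were not tested. The X chromosome, with 210 such genes, lay 0.0946 above the autosomes (bootstrap 95% interval 0.0284 to 0.187). There a change cannot be told apart from a difference of sex.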
